A study of Dugesia japonica with 2 samples.

How the data were processed

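The data were single-cell RNA counts from trunk fragments of the freshwater planarian Dugesia japonica, a flatworm that regrows missing body parts from a pool of dividing stem cells. Per the labels' protocols, fragments were taken 5 days after amputation from worms under a control RNA interference treatment (Control RNAi) or RNA interference against the gene DjTcf4 (DjTcf4 RNAi), both collected in 1 batch. Cells were dissociated from pooled tissue, captured on the 10x Chromium platform with version 3 of its 3′ chemistry, and sequenced on an Illumina NovaSeq instrument. Each treatment had 1 library. The number of worms in each pool is not given in the sources used here.

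The deposited values were whole-number counts of unique molecular identifiers (UMIs) per gene and cell, not normalised, and the matrices were written by Cell Ranger 8.0.0, per the file headers. Seurat was also named in the submitters' processing notes, with no role or version. The genome build, the gene annotation and the filters on barcodes are not given in the sources used here. The shallowest cell held 1469 UMIs in the Control RNAi library and 1428 in the DjTcf4 RNAi library, so barcodes below such a level had been left out before deposit. Both matrices covered the same 38792 gene identifiers, of which 28999 began with DJKW and 9793 with Maker. The column for gene names repeated the identifier, and no reference was used here. None of the names in the marker and gene lists fixed before the data were examined could therefore be looked up, with 0 names found. For that reason clusters were compared by number and no cell type was named. The level of the targeted gene, the ratio of epidermal progenitor classes, the shifts of gene lists and the share of cycling stem cells had all been planned, and none of them could be computed.

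Cells with fewer than 500 UMIs or 200 genes were to be removed, which removed 0 cells. Doublets were scored with Scrublet, as included in scanpy, in each library. It called 0 cells in each, less than the 0.5% below which its calls were set aside, so it was taken not to have worked and all cells were kept. Doublets therefore remained in the data.

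Both libraries were clustered together with scanpy 1.11.5 under Python 3.11.15. Counts were scaled to 10000 per cell and transformed as log1p. The 2000 most variable genes, chosen within each library and combined, gave 30 principal components, from which 15 exact nearest neighbours per cell were found. Leiden clustering ran at resolution 1 (igraph 0.11.9) with no integration of the libraries, and clusters were numbered by size. Each cluster was described by its leading identifier, the gene with the highest level over all other cells among those with a UMI in at least 50% of the cluster's cells. Clusters with at least 100 cells in each library were compared.

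With 1 library per treatment there was no replicate check, and no test, p-value or standard error was computed. A share of cells is given with its exact Clopper-Pearson 95% interval, a summed count with its exact Poisson 95% interval, and a ratio of shares or counts with its exact conditional binomial 95% interval (scipy 1.17.1). All these intervals covered counting error only, not differences between worms, dissociations or captures. Ratios were DjTcf4 RNAi over Control RNAi. Gene levels were UMIs summed over cells, per 1000000 UMIs of the library or cluster (CPM), and log2 ratios were taken after adding 1 CPM, which understates ratios of low genes.

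The rule for the identifiers to print was fixed at the same stage as the lists. Where identifiers had no names, it took the 2 lowest and the 2 highest log2 ratios among genes with at least 200 UMIs over both libraries. Leading identifiers were printed only to describe clusters. For the spread of ratios, the variance that counting alone gives was subtracted from the variance over genes, and the square root of the rest is called the excess SD. Within clusters, genes needed at least 100 UMIs. Random splits of the cells of 1 library in a cluster were treated in the same way.

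The ratio and spread calculations were tested on simulated counts for the 14571 genes of the whole-library comparison, with 200 genes changed by 1 on the log2 scale. Where libraries differed by counting alone, the estimated excess SD was 0.0 and 96.5% of the changed genes' intervals held the true ratio. With an added spread of 0.2 on the log2 scale between libraries, the estimate was 0.199 and the intervals held the true ratio for 60.5% of the changed genes. All of the changed genes had the right direction in both settings (100%). The simulated counts were drawn for whole libraries, with no cells, by the same counting model that the intervals assume. They therefore checked the calculations alone, and not how the intervals or the excess SD behave where UMIs of a gene gather in few cells.

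Before the data were examined, the following other settings had been chosen: all deposited barcodes, a stricter cell filter of 1000 UMIs and 500 genes, no doublet removal, Leiden resolutions of 0.5 and 2, genes centred within each library, 4000 variable genes with 50 components, scaling by the median gene ratio, and a pseudocount of 10 CPM. Further settings were chosen after seeing the data. These were clustering without genes that differed between the libraries, cells with at least 2000 UMIs alone, removal of the 5% of cells with the highest Scrublet scores, leaving out the cell with most UMIs of a gene, leaving out the 5% of cells richest in another cluster's specific genes, and thinning each cell to 1400 UMIs for genes per cell. In another clustering, a cluster was matched to the union of the clusters whose cells lay mostly in it, where the overlap was at least 50% of the joint cells. Genes specific to a cluster, used to read free RNA in other cells, were those at least 8 times as high in it as in every other compared cluster.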

Results

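Cells from regenerating trunk fragments were compared between Control RNAi and DjTcf4 RNAi 5 days after amputation, in a study of when cells differentiate during planarian regeneration. The Control RNAi library held 9588 cells and 25428610 UMIs, and the DjTcf4 RNAi library 10530 cells and 26832732 UMIs. The median cell had 2056 UMIs and 1213 detected genes in the Control RNAi library, against 2004.5 UMIs and 1225 genes in the DjTcf4 RNAi library. After each cell was thinned to 1400 UMIs, which left out 0 cells in each library, the medians were 890 and 922 genes. At least 1 UMI was found for 31411 identifiers in the Control RNAi library and for 31579 in the DjTcf4 RNAi library. The most abundant gene took 9.99% and 8.70% of the UMIs. Because the files did not pair identifiers with gene names, the knockdown of DjTcf4 itself was not checked, and cell populations are given by cluster number and leading identifier.

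The first comparison asked which cell populations took a different share of the fragment under DjTcf4 RNAi. Clusters 4, 7 and 9 held larger shares of the DjTcf4 RNAi library. Together they made up 20.6% of its cells against 14.0% of the Control RNAi cells, a ratio of 1.47 (95% interval 1.37 to 1.57). They were grouped because their own ratios were high, so the joint ratio was bound to exceed 1 and its interval leaves out that choice. Cluster 9, led by DJKW.3667, had the highest ratio, with 4.21% of cells (3.83 to 4.61) against 2.00% (1.73 to 2.30), a ratio of 2.10 (1.77 to 2.50). Cluster 4, led by DJKW.19222, held 9.54% (8.99 to 10.1) against 6.61% (6.12 to 7.13), a ratio of 1.44 (1.305 to 1.597). In cluster 7, led by DJKW.25545, the share was 6.84% (6.36 to 7.34) against 5.40% (4.96 to 5.87), a ratio of 1.27 (1.13 to 1.42). At Leiden resolution 2, cluster 7 was split into parts with ratios of 1.45 (1.26 to 1.68) and 0.946 (0.786 to 1.139). Cluster 6, led by DJKW.5658, was the compared cluster with the lowest ratio, at 5.07% (4.66 to 5.51) against 8.35% (7.81 to 8.93), or 0.61 (0.54 to 0.68). The 11 genes specific to cluster 6, or to it and cluster 8, had a median ratio of 0.912 (0.723 to 1.001 over clusters) in the cells of the other compared clusters, where their UMIs include free RNA.

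**Figure D1:**
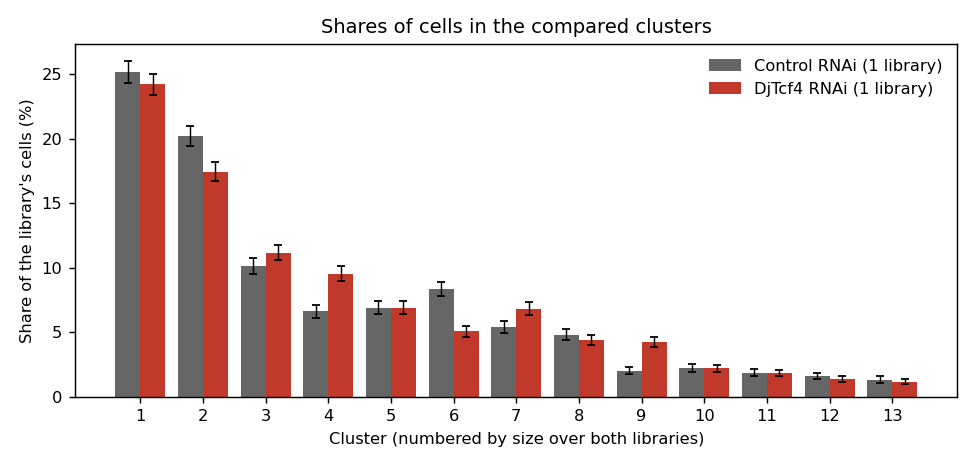
Share of each library's cells (%) in the 13 compared clusters, for the Control RNAi library (grey bars) and the DjTcf4 RNAi library (red bars). Error bars are exact 95% binomial intervals that cover counting error only. Cluster 6 stands at 8.35% and 5.07%, and cluster 9 at 2.00% and 4.21%.

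In all, 22 clusters were found, of which 13 had at least 100 cells in each library. These held 96.5% of the Control RNAi cells and 96.3% of the DjTcf4 RNAi cells. The counting interval of the share ratio lay above 1 in 4 of the 13 and below 1 in 2, and included 1 in the other 7. Besides the clusters already named, cluster 3, led by DJKW.27990, had a ratio of 1.103 (1.01 to 1.20), and cluster 2, led by DJKW.21716, a ratio of 0.86 (0.81 to 0.92). At resolution 2 cluster 2 was split into parts with ratios of 0.29 (0.25 to 0.33) and 1.397 (1.264 to 1.545) among others. Cluster 1, the most populous, held 24.2% of the DjTcf4 RNAi cells and 25.1% of the Control RNAi cells, a ratio of 0.96 (0.91 to 1.02). At resolution 2 cluster 1 held parts with ratios of 0.31 (0.28 to 0.34) and 2.21 (1.99 to 2.46) among others. A further part, with 62.9% of its cells in cluster 1, had a ratio of 2.84 (2.36 to 3.42). The libraries were clustered with no integration. Whether such parts, here and in clusters 2 and 7, are separate populations or the same cells split by library was not tested. Clusters 1 and 2 together held 41.6% of the DjTcf4 RNAi cells and 45.3% of the Control RNAi cells, a ratio of 0.92 (0.88 to 0.96). Cells of cluster 1 were the shallowest among the compared clusters, with a median of 1597 UMIs in the Control RNAi library and 1605.5 in the DjTcf4 RNAi library. Cluster 5, led by DJKW.22458 and the deepest, had a ratio of 0.999 (0.897 to 1.11). Among cells with at least 2000 UMIs, the ratio was 1.30 for cluster 1 and 1.01 for cluster 3. The 9 small clusters held 332 Control RNAi cells and 387 DjTcf4 RNAi cells.

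Some of these clusters bordered on each other in the neighbour graph. Clusters 9 and 12 shared 0.93 of the link weight that random linking would give, the highest value of the 78 pairs of compared clusters. Both changed with the processing, with overlaps of 58.3% and 51.7% with the main clusters under the stricter cell filter. Whether cells passed from 1 to the other was not examined. Cluster 12, led by DJKW.16507, had a share ratio of 0.869 (0.689 to 1.097), which became 1.41 under the stricter cell filter, a setting that removed 5 cells. Counted together, clusters 9 and 12 held 5.60% of the DjTcf4 RNAi cells and 3.61% of the Control RNAi cells, a ratio of 1.55 (1.36 to 1.78). Clusters 6 and 8 shared 0.63 of the random link weight. Cluster 8, led by DJKW.21189, held 4.38% against 4.81% (ratio 0.91, 0.80 to 1.04), and clusters 6 and 8 together held 9.45% against 13.2%, a ratio of 0.72 (0.66 to 0.78). The genes that defined each compared cluster had median log2 ratios within it between -0.19, in cluster 6, and 0.21, in cluster 12. When the cells were clustered without the 407 genes whose counting interval lay beyond 0.5 on the log2 scale in some compared cluster, the ratios were 1.47 for cluster 4, 1.16 for cluster 7, 2.06 for cluster 9 and 0.61 for cluster 6.

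**Figure D2:**
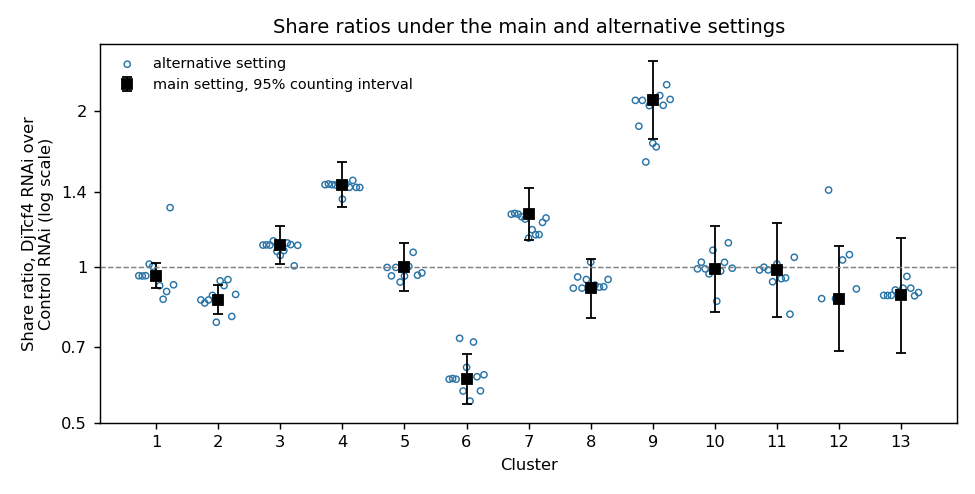
Ratio of each compared cluster's share of cells, DjTcf4 RNAi over Control RNAi, on a log axis. Black squares with bars are the main setting with its 95% counting interval and blue circles the alternative settings. Cluster 6 lies at 0.61 and cluster 9 at 2.10, and the circles of both stay on the same side of the dashed line at 1 as the square.

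The second comparison asked which genes differed in level between the libraries. Among 14571 genes with at least 200 UMIs, DJKW.22146 had the lowest log2 ratio, -1.90. It had 86.2 CPM (82.6 to 89.9) in the Control RNAi library, from 2192 UMIs, and 22.4 CPM (20.6 to 24.3) in the DjTcf4 RNAi library, from 601 UMIs, a ratio of 0.26 (0.24 to 0.28). It was lower under DjTcf4 RNAi in 13 of the 13 compared clusters. Its level under Control RNAi lay between 58.0 CPM in cluster 6 and 129 CPM in cluster 2, and free RNA was not subtracted, so the clusters are not separate observations of its expression. DJKW.4709 had 10.4 CPM (9.20 to 11.8) against 2.65 CPM (2.07 to 3.34), a ratio of 0.25 (0.19 to 0.33), and was lower in 5 of the 5 clusters where it had at least 20 UMIs, with the same limit. Its highest level was in cluster 6, at 31.2 CPM under Control RNAi and 9.88 CPM under DjTcf4 RNAi.

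Of the 2 genes with the highest log2 ratios, DJKW.14308 had 1.81 CPM (1.32 to 2.41) under Control RNAi and 12.9 CPM (11.6 to 14.3) under DjTcf4 RNAi, a ratio of 7.13 (5.23 to 9.92). In cluster 5 it had 2 UMIs against 102 UMIs, and 1 DjTcf4 RNAi cell held 44 UMIs. DJKW.9224 had 18.1 CPM (16.5 to 19.9) against 60.8 CPM (57.9 to 63.8), a ratio of 3.35 (3.02 to 3.73). The cluster shares alone would give DJKW.9224 a log2 ratio of 0.40, against the observed 1.69. Its level was highest in cluster 9 in both libraries, at 219 CPM under Control RNAi and 443 CPM under DjTcf4 RNAi, and cluster 1 had 26.4 CPM and 59.3 CPM. Free RNA was not subtracted, and the genes specific to cluster 9 had a median ratio of 1.35 (1.17 to 1.54 over clusters) in the cells of other clusters, so levels of DJKW.9224 outside cluster 9 are not separate observations of expression.

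**Figure D3:**
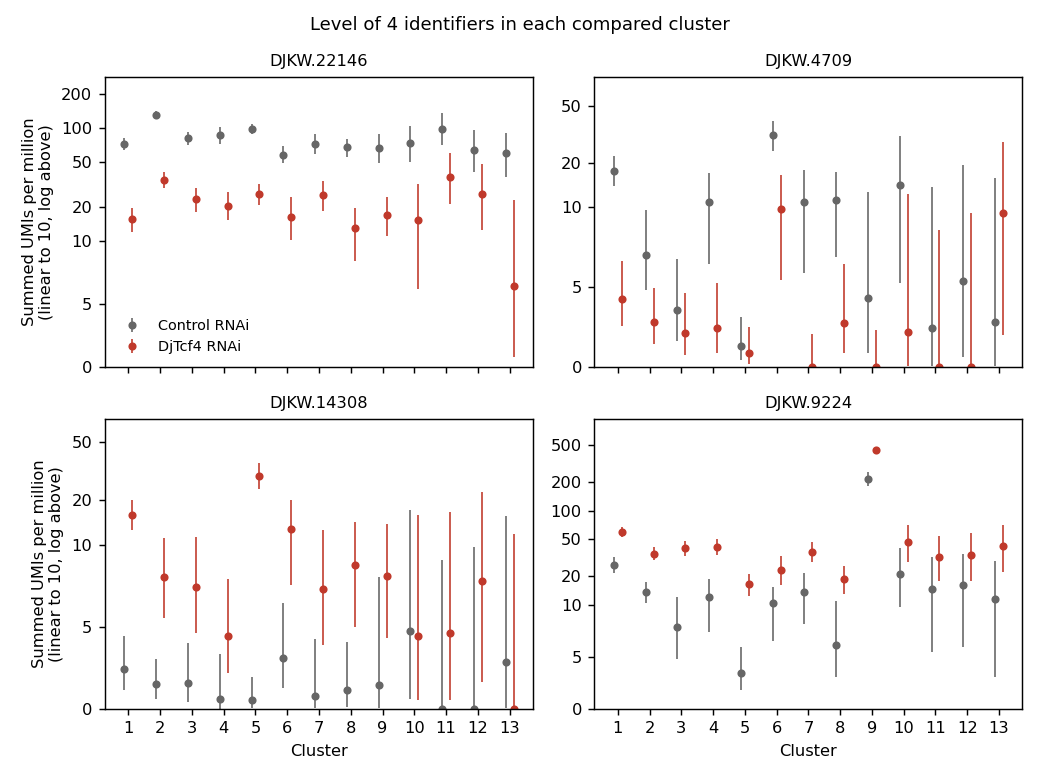
Level in CPM (linear to 10 and log above) of the 4 identifiers in each compared cluster, for Control RNAi (grey) and DjTcf4 RNAi (red), with exact 95% Poisson intervals that cover counting error only. DJKW.22146 is lower in all 13 clusters under DjTcf4 RNAi, and DJKW.9224 reaches 219 CPM and 443 CPM in cluster 9.

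Across all 14571 genes the log2 ratios had an SD of 0.24, of which counting gave 0.11, and the excess SD was 0.21. From the 1st to the 99th percentile the log2 ratios ran from -0.50 to 0.79, with a median of 0.03. The ratios expected from the cluster shares alone had an SD of 0.07 and correlated with the observed ones at r = 0.53 across genes. The squared r, 28.3%, holds for a fitted line, and is not the part of the variance that the expected ratios give as they stand. Genes are not independent replicates, so r describes these libraries.

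Within clusters, the excess SD between the libraries ran from 0.18 to 0.36. Random splits of the cells of 1 library within a cluster gave 0.07 to 0.40. The value between the libraries exceeded those of both libraries' own splits in 11 of the 13 clusters. Extreme ratios within clusters often rested on a single cell. For the gene with the highest log2 ratio in each cluster, leaving out the cell with most of its UMIs in each library took away over 50% of the log2 ratio in 5 of the 13 clusters, and for the gene with the lowest in 3 of the 13. DJKW.22146 was the gene with the lowest ratio in 5 clusters.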

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

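The alternatives on genes left out of clustering, on cells with at least 2000 UMIs and on high Scrublet scores, and those without a top cell, were chosen after seeing the data. For the share ratios, 11 alternatives gave 129 values. Of these, 115 stayed within the counting interval, 14 lay outside it and 0 changed the direction of a ratio whose interval excluded 1. Using all deposited barcodes or no doublet removal removed nothing, so these say nothing about stability. Values outside the interval were 1.41 for cluster 12 with the stricter cell filter; 0.73 for cluster 6 and 1.60 for cluster 9 at resolution 0.5; 0.78 for cluster 2 at resolution 2; 0.94 for cluster 2 and 1.74 for cluster 9 with genes centred in each library; and 1.71 for cluster 9 with 4000 variable genes. Without the 3378 genes whose log2 ratio exceeded 0.5 in size they were 0.87 for cluster 1 and 0.72 for cluster 6, and without the 407 genes whose interval lay beyond it 0.90 for cluster 1 and 0.95 for cluster 2. Among cells with at least 2000 UMIs they were 1.30 for cluster 1, 0.80 for cluster 2 and 1.01 for cluster 3. The cause was not tested. In 14 cases no cluster matched, among them cluster 12 under 5 alternatives. Without the 3378 genes, clusters 2, 5, 8, 10, 11, 12 and 13 had no match, so that setting says nothing about their shares. Of 24 values for the 4 printed identifiers, 20 stayed within their counting intervals, placed around the log2 ratio after 1 CPM was added. A pseudocount of 10 CPM shrank the log2 ratios to -1.57 for DJKW.22146, -0.69 for DJKW.4709, 0.96 for DJKW.14308 and 1.33 for DJKW.9224, by its own construction. The planned results on the targeted gene, epidermal progenitors, gene lists and cycling cells had no value in any setting. No paired analysis was possible because each treatment had 1 library and no result came from a test. The highest log2 ratio of a gene within a cluster, from 2 and 102 UMIs in cluster 5, was 4.31. It went to 3.11 with a pseudocount of 10 CPM and to 3.804 without the top cell. The lowest, from 99 UMIs and 1 UMI in cluster 13, was -6.07 and went to -4.46 and -4.17. Their counting intervals hold these values only as placed around the log2 ratio after 1 CPM was added. Both ratios set no firm size.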

Other observations

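All tests of explanations for cluster shares were chosen after those shares had been seen. The tests of cluster shares and of few cells for DJKW.22146 were set before their results were seen.

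Cells of cluster 5 were the deepest among the compared clusters in both libraries, with a median of 5290.5 UMIs under Control RNAi and 4412.5 under DjTcf4 RNAi, while their share was level. After thinning to 1400 UMIs, the median number of genes per cell in that cluster was 948.5 and 957. In cluster 1 the thinned medians were 832 and 881 genes, and in cluster 6 they were 716 and 761.5. The log2 ratios of genes in pairs of clusters correlated across genes at a median r of 0.34, between 0.15 and 0.54 over the 78 pairs. Part of the difference in counts between the libraries was thus shared by clusters of different composition. Free RNA was not subtracted and can enter every cluster of a library, so this need not mean a shared change of expression.

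Cluster 6 held a smaller share of the DjTcf4 RNAi library. Among cells with at least 2000 UMIs its ratio was 0.576 (0.499 to 0.665), so the smaller share was not confined to shallower cells. This does not decide on depth. Cells of cluster 6 had a median of 2173.5 UMIs under DjTcf4 RNAi against 2313 under Control RNAi, and a higher cut would also leave out more of the former. Counted with its neighbour, cluster 8, the ratio was 0.72 (0.66 to 0.78), which argues against a shifted boundary between these clusters. The border with cluster 1, which held 2.75% of the link weight of cluster 6 against 2.77% for cluster 8, was not examined. Loss of these cells in dissociation or capture may account for the share: the 11 genes specific to cluster 6, or to 6 and 8, had a median ratio in the other compared clusters of 1.01 (0.911 to 1.047 over clusters), without the 5% of cells richest in them and relative to clusters 6 and 8, but how closely such levels follow the number of cells in the tissue is not known, so the values do not decide. Without these corrections the median was 0.912 (0.723 to 1.001), and an effect of the RNAi on the population remained open.

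Clusters 4, 7 and 9 held larger shares of the DjTcf4 RNAi library. Among cells with at least 2000 UMIs the ratio was 1.426 (1.250 to 1.628) for cluster 4 and 2.25 (1.86 to 2.75) for cluster 9. Both lay past the bound of 1.1 set for depth, while for cluster 7 the ratio was 1.220 (1.045 to 1.426). The larger shares were thus not confined to shallower cells. Such a cut cannot remove a difference in depth, so depth stayed open. Median UMIs under DjTcf4 RNAi and Control RNAi were 3185 and 2914.5 in cluster 9, 2137 and 2175.5 in cluster 4, and 2030 and 2098 in cluster 7. A loss of other cells would raise every remaining share alike. The highest upper bound among the other 10 compared clusters was 1.217 in all cells and 1.622 in those with at least 2000 UMIs. The lower bounds of cluster 9, 1.77 and 1.86, lay above both. Those of cluster 4, 1.305 and 1.250, lay only above the former, and those of cluster 7, 1.129 and 1.045, above neither. These bounds hold for the clusters at resolution 1. At resolution 2, parts that lay mostly in cluster 1 had ratios of 2.21 (1.99 to 2.46) and 2.84 (2.36 to 3.42). The comparison therefore does not set cluster 9 apart from all other cells, and a loss of other cells stayed open. Under selective capture, a cluster's specific genes were to stay level in other clusters, with a median ratio of 1.1 or below. A ratio above 1.1 in each other cluster was to speak against it. The specific genes of clusters 4 and 7 were read in other clusters, without the 5% of cells richest in them and relative to the cluster itself. The median ratios were 1.238 (0.986 to 1.363 over clusters) and 1.201 (1.074 to 1.432). Neither rule was met, so capture stayed open for clusters 4 and 7. For cluster 9 the median was 1.41 (1.22 to 1.68), and all values lay above the bound of 1.1. With all cells kept, genes specific to cluster 11, with a share ratio of 0.987, had 1.11 in other clusters against 0.849 in their own. For cluster 3 the values were 1.06 and 0.81, for cluster 13 1.07 and 1.06, and for cluster 12 0.994 and 1.454. A higher ratio elsewhere than in the cluster itself was thus not particular to clusters with clearly larger shares. How closely such levels follow the number of cells in the tissue is not known, so capture stayed open for cluster 9 too. An effect of the RNAi remained open for all 3. Counted with cluster 12, cluster 9 had a ratio of 1.55 (1.36 to 1.78). This argues against the boundary between these clusters as the whole cause of the larger share, while the size of the change in cluster 9 alone remained open.

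DJKW.22146 was lower in the DjTcf4 RNAi library, in all 13 compared clusters, which are not separate observations where free RNA was not subtracted. The cluster shares alone would give a log2 ratio of -0.019 against the observed -1.90. Its 2192 UMIs in the Control RNAi library came from 1851 cells, with at most 5 in any cell. Leaving out the 10 Control RNAi cells with most of its UMIs could therefore change little, and gave a log2 ratio of -1.87. Neither shares nor a few cells account for the lower level. The RNAi and any other difference between the libraries cannot be told apart, since there was 1 library per group. Whether this identifier is the targeted gene was not examined, as no sequence or name was used here.

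DJKW.8946, singled out after its values were seen, had 502 UMIs in cluster 5 under Control RNAi and 18 under DjTcf4 RNAi, but 483 of the former came from 1 cell of 6845 UMIs. In the whole libraries it had 932 and 1273 UMIs, and without the cell with most in each library, 449 and 672. At resolution 2, cluster 4 was split into parts with share ratios of 1.386 (1.222 to 1.573) and 1.585 (1.335 to 1.885). Pairs of genes with consecutive identifiers had a median correlation of their levels over the 13 compared clusters of 0.263 against 0.185 for random pairs, and 2.56% against 0.47% had r above 0.9, over 7060 pairs each.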
